A study of Mus musculus with 6 samples.

How the data were processed

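Total RNA from newborn mouse striatum was sequenced in 6 libraries, 3 from controls with floxed Sp9 and 3 from mutants with floxed Sp9 and Drd2-Cre. The strain background was mixed, per the labels. The authors deposited 1 table for the series, with 1 row per Ensembl gene and, per the file headers, an FPKM column and a count column for each library. FPKM is the number of fragments per kilobase of transcript, scaled to the number of mapped fragments. TopHat (version not given) and Cufflinks 2.1.1 are the tools, and GRCm38.p4 the genome build, that are listed per the submitters' processing notes. The annotation release, the treatment of reads that map to several places and the use of strand are not given in the sources used here. Where genes overlap, as Sp9, Cir1 and Scrn3 do, fragments of one may therefore have been counted for another.

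The deposited count columns were treated as a signal and not as raw counts, because their values are not whole. In each library, 97.6 to 97.9% of the values above 0 lay within 0.1 of a whole multiple of the most frequent low value, which ran from 0.970 to 1.15 between libraries. Values under 0.01 are vanishing estimates and were left out of this share. The columns thus hold estimated fragments multiplied by 1 factor per library, called scaled counts here. Their totals ran from 18714356 to 19274505, and dividing by the step gave 16237067 to 19457744 fragments per library. The gene Scrn3, for example, reached 524 fragments in its highest library and Grik3 4751. FPKM totals differed more between libraries, since the table holds very short genes where a single fragment gives a large FPKM. No count test was run.

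Gene symbols came from GENCODE release M21 and matched 46483 of the 47062 identifiers; positions are those of that release on GRCm38. Library columns were matched to groups by the sample codes in the labels. Pairs of libraries had correlations of log2 values between 0.825 and 0.859, and no pair held identical values beyond chance ties.

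For the comparison, limma 3.58.1 in R 4.3.3 was fitted to log2(FPKM + 0.5) with a trend of variance on level, over all 6 libraries with no covariate. Genes with a mean FPKM of at least 0.5 were kept (16666 genes), and p-values, two-sided, were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes are on the log2(FPKM + 0.5) scale, which understates those of low genes. The study's own rule, a fold of at least 2 with an unadjusted p of at most 0.05, was counted beside it. Before the data were examined, 31 gene lists were fixed: indirect and direct pathway neurons, genes shared by both, striosome, matrix, the Sp family, neighbours of Drd2, ganglionic eminence progenitors, the cell cycle, olfactory bulb neuroblasts, interneurons of the medial and caudal eminences, cortical glutamatergic neurons, septum, thalamus and hypothalamus, astrocytes, the oligodendrocyte lineage, microglia, vessel cells, meningeal fibroblasts, red blood cells, choroid plexus, ependyma, p53 targets, immediate early genes, retinoic acid, neuropeptides and opioid receptors, axon guidance, synaptic vesicles, interferon response and sex chromosomes. All but the last were tested with camera at a preset correlation of 0.01 and again with an estimated one, and with fry. The mean log2 values of the 2 projection neuron lists were compared per library by an exact permutation test.

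Named genes followed a rule fixed in advance. It takes Sp9; the 10 that rose most and the 10 that fell most among genes past the threshold whose groups do not overlap; and, from each list, members past the threshold and up to 4 others with the smallest p. Predicted genes, pseudogenes and unnamed identifiers were counted but not named. Since fewer than 10 passed in each direction, the places were filled by p from genes that met the study's rule. Every measured member of the 2 projection neuron lists may be named. Some genes that the rule takes are not reported here. Fig4 and Ccdc114 were named after their values were seen, as were Cir1 and other neighbours of Sp9. Ankk1, from the list of Drd2 neighbours, lay under the filter on mean FPKM and was also named then.

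The alternatives were pseudocounts of 0.1 and 1, no filter, a mean FPKM of at least 1, quantile normalization, median-ratio scaling, the replicate number as a block, robust limma, a sex covariate and each library left out in turn. Control replicate 3 was the only male library, so the sex covariate gave the same fold changes as leaving that library out. Sex cannot be told apart from that library. After seeing the data, 2 were added: log2(scaled count + 1) for genes with a mean of at least 10, and the FPKM fit limited to genes with a mean scaled count of at least 10. The steps were tested on simulated data with the real means and library sizes and a dispersion of 0.00215, in which 200 genes were changed. For mutant against control on FPKM (16568 simulated genes tested), the fit recovered 74% of genes changed 1.5-fold, 93.9% of those changed 2-fold and 100% of those changed 4-fold. It called 13 unchanged genes, against 32 with the added filter (15111 genes) and 22 on scaled counts (16124 genes). All simulated genes shared 1 dispersion and kept a fixed ratio of FPKM to count, and genes of few fragments were not among those changed. In the real data P2ry1 was 4.19-fold lower at an adjusted p of 0.259 (limma). Gfra1 was 3.50-fold higher at 0.376. The recovered shares therefore do not carry over to genes that vary more between libraries.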

Results

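RNA was sequenced from the striatum, with the subventricular zone included, of newborn mice (postnatal day 0) that carried floxed alleles of Sp9. Sp9 encodes a zinc finger transcription factor of the Sp family. The 3 control libraries came from littermates with the floxed alleles and no Cre, and the 3 mutant libraries from animals that also carried Drd2-Cre, a Cre recombinase driven by regulatory sequence of the dopamine D2 receptor gene. Drd2 marks the striatopallidal, or indirect pathway, projection neurons, so the deletion was aimed at those cells and their precursors. The deposited table lists 47062 genes, and the libraries held between 16237067 and 19457744 fragments in genes, as estimated from the most frequent low value of the scaled counts. After a filter on low values, 16666 genes were tested. The labels do not say whether each library came from 1 animal, so p-values measure the spread between these libraries.

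The comparison of mutant with control asks which genes differ in bulk striatum when Drd2-Cre is present with the floxed alleles. No group carried Drd2-Cre without them, so effects of the Sp9 deletion and of the Cre transgene cannot be told apart. Bulk tissue also does not show in which cells a gene changed. Sp9 itself (ENSMUSG00000068859; GRCm38 chromosome 2, 73271925 to 73284706, plus strand) had an FPKM of 20.1, 19.0 and 17.3 in control replicates 1 to 3 and of 8.37, 7.93 and 9.67 in mutant replicates 1 to 3. The means were 18.8 ± 1.38 and 8.65 ± 0.906 (SD, n = 3 each), and the log2 fold change was -1.08 ± 0.09 (SE). The adjusted p was 0.0567 with limma, just outside the threshold of 0.05, and the exact two-sided permutation test gave 0.1, the smallest p that 3 against 3 libraries allow. On the authors' scaled counts, an alternative chosen after seeing the data, the log2 fold change of Sp9 was -1.32 and the adjusted p was 0.00635 with limma. The labels do not give the deleted part of Sp9, and fragments from exons outside it would still be counted. The tissue also holds cells at which the deletion was not aimed, and Cir1 overlaps the end of Sp9. The sources of the remaining Sp9 signal were not separated.

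Of the 3 genes with established names past the threshold, 2 were lower and 1 was higher in the mutants. Adora2a (ENSMUSG00000020178; chromosome 10, 75316877 to 75334784), which encodes an adenosine receptor that marks these cells, fell from an FPKM of 44.3 ± 3.26 to 4.11 ± 1.18 (SD, n = 3 each), a 9.9-fold decrease (log2 fold change -3.31 ± 0.19, adjusted p = 0.00852, limma). Grik3 (ENSMUSG00000001985; chromosome 4, 125490700 to 125714173), a kainate-type glutamate receptor subunit, fell from 25.4 ± 1.81 to 11.1 ± 0.736 (log2 fold change -1.16 ± 0.08, adjusted p = 0.0156). Scrn3 (ENSMUSG00000008226; chromosome 2, 73312601 to 73337818), a gene of the secernin family that lies downstream of Sp9 and overlaps the start of Cir1, rose from 2.55 ± 0.398 to 11.6 ± 1.3 (log2 fold change 1.99 ± 0.13, adjusted p = 0.0156). In all 3 genes every mutant library lay outside the range of the controls.

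**Figure D1:**
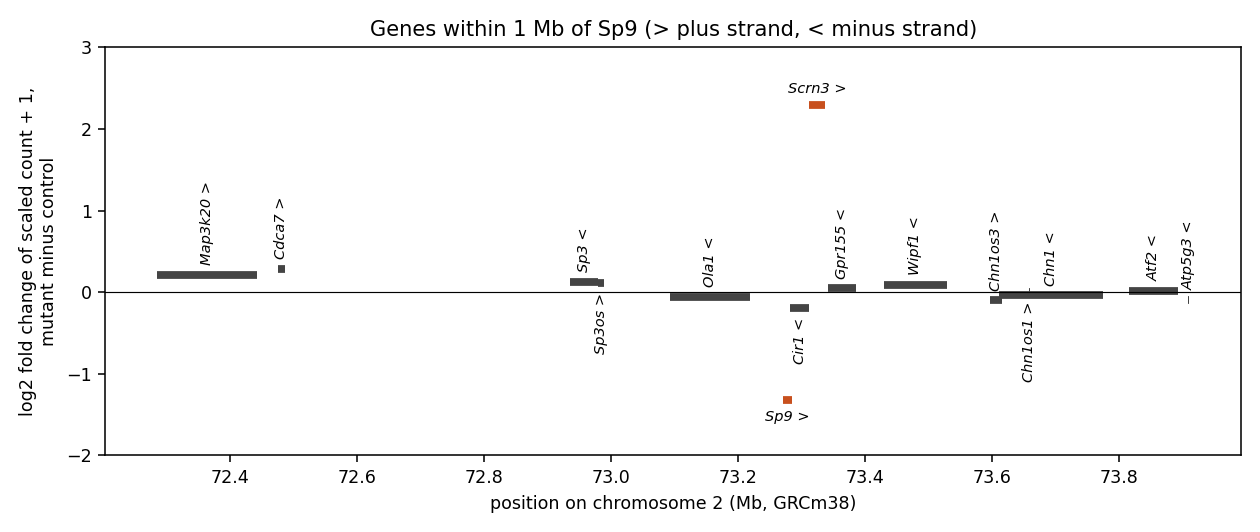
Genes within 1 Mb of Sp9 on chromosome 2, each drawn to scale from its start to its end (x axis, Mb, GRCm38) at its log2 fold change in scaled counts + 1, mutant minus control (y axis). Sp9 lies at -1.32 and Scrn3 at 2.29, and the 13 other measured genes lie between -0.20 and 0.29.

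These 3 were the only genes with established names among 10 genes past an adjusted p of 0.05 with limma, 6 higher and 4 lower. The other 7 were predicted or unnamed transcripts listed at 0 in every library of 1 group, and none of them held more than 3 fragments in any library. When genes with a mean scaled count under 10 were also left out, a filter chosen after seeing the data, 7 genes passed. These were Scrn3 and Sult2b1, which were higher, and Adora2a, Grik3, Gpr6, Sp9 and Fig4, which were lower. On the scaled counts 23 genes passed, 8 higher and 15 lower, and they included P2ry1, Ptprm, Sox9, Efna5, Gfra1 and Nuak2. With 1 library left out, the direction of Adora2a, Grik3 and Scrn3 on FPKM was kept, but the limma call was lost for Adora2a without any 1 control or mutant replicate 1 (adjusted p up to 0.0853), for Grik3 without control replicate 2 or 3 or mutant replicate 1 or 3 (up to 0.101), and for Scrn3 without control replicate 1 or 3 or mutant replicate 1 or 2 (up to 0.117). With sex as a covariate their adjusted p were 0.0564, 0.0664 and 0.0923, and with the replicate block 0.220, 0.180 and 0.220.

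**Figure D2:**
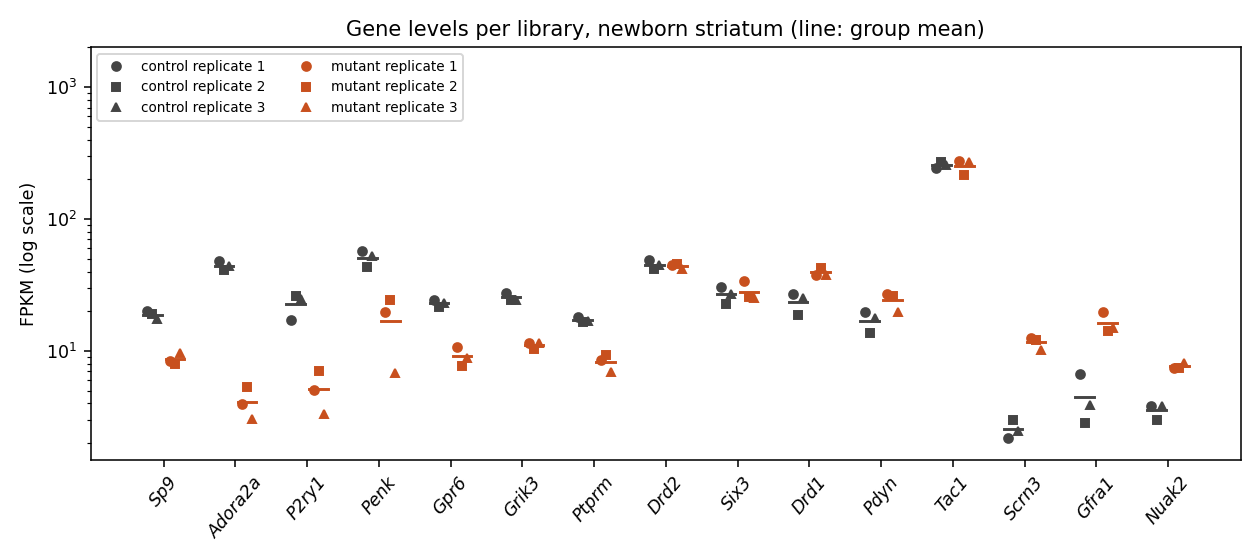
FPKM on a log axis for 15 genes in each of the 3 control (grey) and 3 mutant (orange) libraries, with a line at each group mean. Adora2a lies near 44.3 in the controls and near 4.11 in the mutants, whereas the 6 values of Drd2 share 1 range.

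The list of indirect pathway genes had 12 measured members. Of these, 2 fell past the threshold over all genes (Adora2a and Grik3), and 7 fell when p was adjusted over the list alone, with no member that rose. The further 5 were P2ry1, a purinergic receptor (22.6 ± 4.84 to 5.14 ± 1.86 FPKM), Penk, the precursor of enkephalin (50.8 ± 7.15 to 16.9 ± 9.08), Gpr6 (23.0 ± 1.44 to 9.09 ± 1.55), the receptor phosphatase Ptprm (17.2 ± 0.817 to 8.26 ± 1.23) and Nt5e, an enzyme that makes adenosine (1.15 ± 0.246 to 0.695 ± 0.0212; SD, n = 3 in each case). Penk varied most among the mutants, with 19.7, 24.3 and 6.79 in replicates 1 to 3. Drd2, the gene whose regulatory sequence drives Cre, had an FPKM of 45.0 ± 3.25 in the controls and 44.4 ± 1.97 in the mutants (log2 fold change -0.02, 95% interval -0.18 to 0.14). The transcription factor gene Six3 had 26.8 ± 4.01 and 28.2 ± 4.70. Adk, Plxdc1 and Cd4 did not pass the test either. As a set the list was lower (camera adjusted p = 2.36e-10, limma), with an adjusted p = 0.280 with an estimated correlation between genes; fry, which tests the list by itself, gave an adjusted p of 0.0253.

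The list of direct pathway genes, which mark the striatonigral projection neurons, went the other way. None of its 14 members passed over all genes with limma, and 4 were higher and 1 lower at an unadjusted p under 0.05; adjusted over the list alone, 3 rose and 1 fell. The dopamine D1 receptor gene Drd1 rose from an FPKM of 23.7 ± 4.31 to 39.3 ± 2.91 (SD, n = 3 each), a 1.66-fold difference, and Sfxn1 and Tmem158 rose 1.36-fold and 1.29-fold. Isl1, a transcription factor gene of these neurons, fell from 64.3 ± 3.57 to 54.7 ± 1.34. Pdyn, the precursor of dynorphin, had 17.0 ± 2.99 and 24.2 ± 3.96 and was not past the threshold, and Tac1, which encodes substance P, had 256 ± 12.6 and 254 ± 34.2. The list was higher as a set with camera at the preset correlation (adjusted p = 0.00489, limma). With an estimated correlation the camera adjusted p was 0.575, and fry gave an adjusted p of 0.331. Without control replicate 1 the camera adjusted p at the preset correlation was 0.0966. The difference between the mean log2 values of the indirect and direct lists was -0.95 ± 0.03 in the controls and -2.09 ± 0.11 in the mutants (SD, n = 3 each), a shift of -1.14. The exact two-sided permutation p was 0.1, the smallest this design can give.

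**Figure D3:**
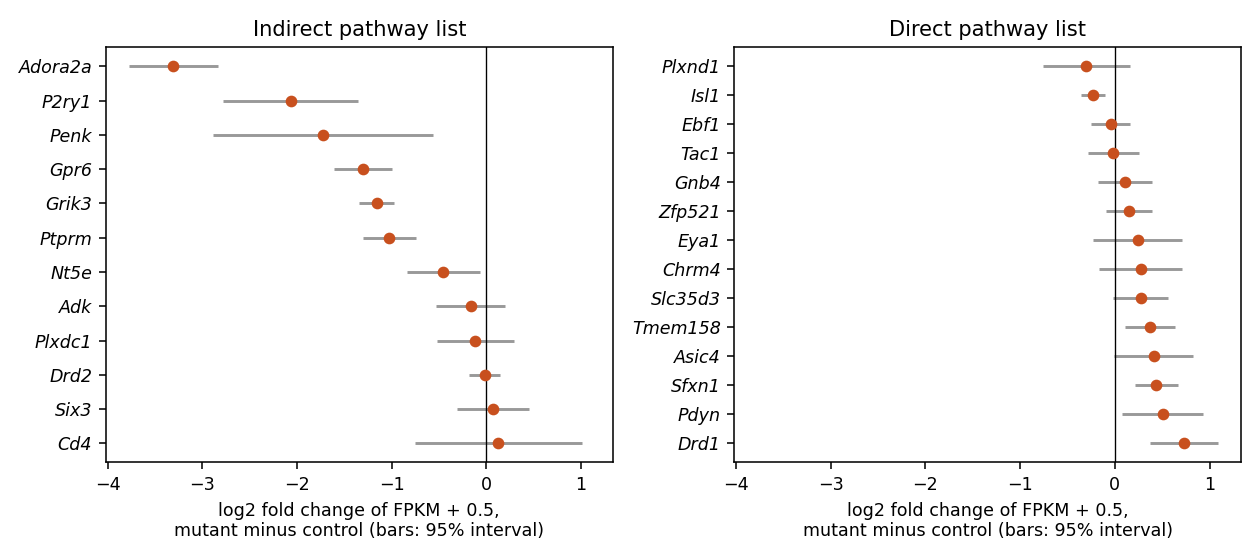
Log2 fold change of FPKM + 0.5, mutant minus control, for the 12 measured members of the indirect list and the 14 of the direct list; points are estimates and bars 95% intervals from the limma fit. Adora2a stands lowest at -3.31, Drd2 lies at -0.02 and Drd1 highest in the direct list at 0.73.

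Among 28 genes shared by both classes of projection neuron, none passed over all genes with limma, 1 was higher and 6 were lower at an unadjusted p under 0.05, and 2 fell when adjusted over the list alone. They included the transcription factor gene Foxp1 (331 ± 11.0 to 259 ± 9.03 FPKM; SD, n = 3 each). As a set this list was lower, with a mean log2 fold change of only -0.07 (camera adjusted p = 0.0253, limma; adjusted p = 0.575 with an estimated correlation). Its camera adjusted p was 0.184 with sex as a covariate and 0.185 without control replicate 3 (mean -0.04), the only male library, so these are not separate checks. It was 0.578 without mutant replicate 3 (mean -0.03). The 7 striosome and 6 matrix genes gave camera adjusted p of 0.966 and 0.0681; the mean of the striosome genes was 0.025 (-0.03 to 0.08 with 1 library left out) and their median -0.095, so these differ in sign. The matrix list, higher by a mean of 0.24, passed with quantile normalization (0.0482), the replicate block (0.0312), scaled counts (0.0130) and the added filter (0.0440). It also passed without mutant replicate 3 (0.000200, mean 0.42), whereas without mutant replicate 2 its mean was 0.10 (0.504). With an estimated correlation the camera adjusted p of the matrix list was 0.581. In the Sp family, Sp9 fell and Sp3 rose (27.7 ± 1.03 to 32.2 ± 1.97 FPKM) when adjusted over the list of 6 alone. That list holds the targeted gene Sp9 itself, which eases the adjustment for Sp3. On scaled counts the log2 fold change of Sp3 was 0.13, with groups that overlap and an adjusted p over all genes of 0.807 (limma). Without Sp9 the family gave a camera adjusted p of 0.385 with an upward direction, against a mean over all 6 of -0.07.

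Beyond these lists, the named genes include those with at least a 2-fold change and an unadjusted p of at most 0.05, the rule of the study's design. By that rule 29 genes were higher and 28 lower. The other splits of the 6 libraries into 3 and 3 gave between 44 and 70 genes, against 57 in the real one. None of the genes from Gfra1 to Necab1 below passed an adjusted p of 0.05 in the limma fit on FPKM over all 16666 genes. Sult2b1 did with robust limma (0.0320) and with the added filter (0.0229). On scaled counts Nuak2 (0.00839), Sox9 (0.0195) and Gfra1 (0.0349) passed with limma, and the others, with Sult2b1 at 0.109, did not. Each of these genes had control and mutant libraries that did not overlap in FPKM. On the higher side, Gfra1, a receptor subunit for the neurotrophic factor GDNF, had 4.47 ± 1.96 in the controls and 16.2 ± 3.0 in the mutants. Nuak2, a kinase gene, had 3.56 ± 0.497 and 7.63 ± 0.417, the sulfotransferase gene Sult2b1 had 0.542 ± 0.170 and 3.39 ± 0.569, and the sialyltransferase gene St3gal1 had 4.89 ± 1.40 and 11.0 ± 0.943 (SD, n = 3 each). Dync1i1, Sstr2 and Cdh4 had fold differences of 2.16, 2.14 and 2.17. On the lower side, Sox9, a transcription factor gene of glia and progenitors, had 15.1 ± 1.46 and 6.85 ± 1.37, and the calcium-binding protein gene Necab1 had 26.4 ± 5.72 and 11.3 ± 2.95. Over all 16666 genes, 11.4% had groups that did not overlap, against 10% by chance, and 941 had an unadjusted p under 0.05.

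Markers of other cells in the dissected tissue mostly had small differences, and no member passed with limma over all genes or when adjusted over its list alone. At an unadjusted p under 0.05, 2 genes of the medial ganglionic eminence (Nxph1 and Lhx8), 1 of progenitors (Dlx5) and 1 of the choroid plexus (Ttr) were higher. The list of interneurons from the medial ganglionic eminence was higher as a set, with all 14 estimates above 0 and a mean log2 fold change of 0.27 (camera adjusted p = 9.86e-05, limma; adjusted p = 0.575 with an estimated correlation); the mean was 0.18 without control replicate 1. Npy, for example, had an FPKM of 189 ± 35.7 and 240 ± 19.8, and Lhx8 had 8.39 ± 1.83 and 12.1 ± 1.69 (SD, n = 3 each). Lists of microglia (mean log2 fold change 0.19, camera adjusted p = 0.00829), meningeal fibroblasts (0.25, 0.0253) and septum (0.25, 0.0372) were also higher, each with an adjusted p = 0.575 with an estimated correlation. With 1 library left out, camera adjusted p reached 0.0985 for microglia (without mutant replicate 2), 0.123 for meningeal fibroblasts (without control replicate 3; 0.0920 without mutant replicate 3) and 0.372 for septum (without mutant replicate 2, mean 0.12; also lost without control replicate 1 or 2 or mutant replicate 3). The septum call was also lost with no filter on mean FPKM (0.133, mean 0.18). That of meningeal fibroblasts was lost at a mean FPKM of at least 1 (0.108), with sex as a covariate (0.142) and with the replicate block (0.0560). Astrocyte genes (0.17, 0.0115) and cortical glutamatergic genes (0.50, 0.0115) had an adjusted p = 0.581 with an estimated correlation. The cortical list rested on mutant replicate 3, without which its mean was 0.11 and its camera adjusted p 0.686 (mean 0.91 without mutant replicate 2), and its camera adjusted p was 0.162 without control replicate 3 and 0.164 with sex as a covariate. Astrocyte genes lost their call without control replicate 1 or 3 or mutant replicate 2 or 3 (camera adjusted p up to 0.185, with a mean of 0.09 without control replicate 3 and 0.27 without control replicate 2) and with sex as a covariate (0.184). Lists of cell cycle genes (camera adjusted p = 0.750), ganglionic eminence progenitors (0.285), olfactory bulb neuroblasts (0.116), interneurons of the caudal eminence (0.356), the oligodendrocyte lineage (0.520), vessel cells (0.438), thalamus and hypothalamus (0.590), red blood cells (0.116), choroid plexus (0.503) and ependyma (0.966) did not pass. Some of these passed in other fits: red blood cells with the replicate block (0.0201) and without mutant replicate 1 (0.0126), vessel cells without control replicate 1 (0.0355) and progenitors without mutant replicate 1 (0.0415). Olfactory bulb neuroblasts passed without mutant replicate 2 (0.0335) and on scaled counts (0.0324). Xist and 4 Y-linked genes marked control replicate 3 as male and the other 5 libraries as female. The fit with the sex covariate thus repeats the fit without control replicate 3 and is not a separate check.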

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

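Sp9 stayed lower in the mutants and the indirect list stayed below the direct one by more than in the controls under every alternative run, while several counts and calls moved. The fit on scaled counts and the filter on scaled counts were chosen after seeing the data. The count of changed genes was 10 as reported, 5 with a replicate block (4 higher, 1 lower), 19 with a sex covariate, 23 on scaled counts and between 12 and 21 with 1 library left out. The 19 with the sex covariate included 6 of the 10, and leaving out control replicate 1, control replicate 3, mutant replicate 2 or mutant replicate 3 gave 16, 20, 18 and 21 genes. Named genes past the threshold whose groups do not overlap numbered 3 as reported, 0 with the replicate block, 0 with the sex covariate (2 others passed with groups that overlap), 7 with robust limma, 7 with the filter on scaled counts, 23 on scaled counts and 1 to 4 with 1 library left out, the lowest without mutant replicate 1. The genes at fold 2 numbered 57 as reported, 90 with a pseudocount of 0.1, 37 with a pseudocount of 1, 29 with the filter on scaled counts and 71 to 84 with 1 library left out. Sp9 passed the threshold with a pseudocount of 0.1 (log2 fold change -1.11), a mean FPKM of at least 1 (-1.08), robust limma (-1.08), the filter on scaled counts (-1.08) and scaled counts (-1.32), and ranged from -1.16 to -1.02 with 1 library left out; its limma adjusted p ran from 0.00635 on scaled counts to 0.579 with the replicate block. The shift between the indirect and direct lists was -1.40 with a mean FPKM of at least 1, which leaves fewer members, and -1.17 to -1.07 with 1 library left out. Of the lists, 12 passed with camera as reported, 0 with an estimated correlation, 1 with fry and 7 to 14 with 1 library left out (7 without mutant replicate 3). The indirect list was the 1 that passed with fry, and it passed in each camera fit at the preset correlation. The cause of these moves was not tested, except that fewer libraries or genes entered some fits. Same-numbered libraries deviated from their group means with correlations of 0.0025, 0.037 and 0.043, against -0.068 to 0.033 for the other pairs. Values this small from so few libraries cannot decide whether the numbers pair the samples, so the fit with the replicate block is not set aside. Taking each named gene under each alternative, 2412 results kept their direction and side of the threshold, 18 lost the call, 13 gained it and 32 that were not past it changed sign; for each list with camera these numbers were 437, 28, 12 and 31. Only Adora2a, Grik3 and Scrn3 were past the threshold as reported, so only these 3 could lose a call, under 17 alternatives, and the 18 losses are theirs. Most of the 2412 were genes not past it in either fit. Scalings moved the median of all genes by at most 0.01 on the log2 scale. The depth, with the same 1 fragment worth 0.970 to 1.15 scaled counts, limits statements on genes of a few fragments. Count tests were not run, since the values are not raw counts.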

Other observations

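Further lists describe genes of activity, stress and wiring. Immediate early genes were lower as a set in the mutants, with 12 of 14 estimates below 0 and a mean log2 fold change of -0.25 (camera adjusted p = 0.00252, limma; adjusted p = 0.575 with an estimated correlation). Of these, 1 member fell when adjusted over the list alone, Egr1 (25.4 ± 4.33 to 16.1 ± 0.487 FPKM; SD, n = 3 each), and Fos had 4.30 ± 1.80 and 2.32 ± 0.478. The set call was lost without control replicate 1 (camera adjusted p = 0.102, mean -0.11). Targets of p53 were higher as a set (mean 0.16, camera adjusted p = 0.00829), and the 6 measured interferon response genes were lower (mean -0.44, camera adjusted p = 0.0115), each with an adjusted p = 0.575 with an estimated correlation. Without mutant replicate 3 both calls were lost (camera adjusted p = 0.106 for each), as was that of p53 targets without control replicate 1 (0.0605) and that of interferon genes without control replicate 2 (0.210, mean -0.16). Lists of axon guidance (camera adjusted p = 0.966), synaptic vesicles (0.173), retinoic acid (0.356) and neuropeptides with opioid receptors (0.116) did not pass as sets, although synaptic vesicles did without mutant replicate 2 (0.0121). Single members fell when adjusted over their list alone: Efna5, a ligand of Eph receptors, from 5.98 ± 0.372 to 3.50 ± 0.634 FPKM, and Syp, which encodes synaptophysin, from 138 ± 4.24 to 117 ± 1.75 (SD, n = 3 each).

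The tests on the patterns below, and the split test on scaled counts, were chosen after the results were seen. The members of the indirect list moved apart: Adora2a was lower by more than any other member, while Drd2 was not lower. Less striatal tissue in the mutant dissections would lower direct pathway genes too, but the mean of the direct list was higher by 0.21 ± 0.07 (SE) on the log2 scale. Lists of tissue outside the striatum were mixed, with means of 0.25 for septum, 0.50 for cortical glutamatergic genes and -0.02 for thalamus and hypothalamus. The septum and cortical calls were lost when single libraries were left out. A loss of indirect pathway neurons as the whole cause would lower Drd2, and the lower end of its 95% interval was -0.18. A loss of cells together with extra Drd2 transcripts from the Cre transgene would account for Drd2 alone. Six3, of the same list, was not lower either (log2 fold change 0.07, 95% interval -0.31 to 0.45), and Adk was not lower past its spread (-0.17, -0.53 to 0.20). The combination would need these to come largely from other cells, which was not tested, so it stays open beside a change within the cells. Ttc12, close to Drd2 on chromosome 9, had a log2 fold change of 0.93 in scaled counts (38.6 ± 15.1 to 71.2 ± 5.06, SD, n = 3 each). Its adjusted p there was 0.440 (limma). Ankk1 between them went from 13.1 ± 4.67 to 4.07 ± 1.54, but lay under the filters and was not tested. Neither difference decides on the transgene. The part of the genome in the transgene is not given. The list of Drd2 neighbours (4 measured genes, Drd2 itself among them) gave a camera adjusted p of 0.966. Its mean was 0.11 (0.06 to 0.14 with 1 library left out) and its median -0.016.

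Scrn3 rose beside the targeted gene. It lies on chromosome 2 (GRCm38, 73312601 to 73337818, plus strand), downstream of Sp9, and its start overlaps Cir1 (73283105 to 73312701, minus strand), which also overlaps the end of Sp9. Fragments of Cir1 counted for Scrn3 are argued against, since the gain of Scrn3 (377 mean scaled counts) was 3.61 times the loss of Cir1 (104). A shift of the whole region is argued against as well: the 13 other measured genes within 1 Mb had a median log2 fold change of 0.018 and none outside -0.20 to 0.29. Transcripts that run on from the recombined Sp9 allele into Scrn3 are a candidate source that stays open beside a response of Scrn3 to the genotype; the ratio of FPKM to scaled count of Scrn3 shifted by -0.11 on the log2 scale with overlapping groups, that of Sp9 by 0.20 with groups apart, and reads between the genes were not analysed here.

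The 7 called genes listed at 0 in 1 group (5 higher in the mutants, 2 lower) had FPKM values as high as 20189. They held at most 3 fragments in any library, so each of these FPKM values rests on a few fragments. Genes at 0 in 1 group and above 0 in the other were at least 9 in 8 of the 10 splits of the libraries, the real one with 9 included, and the highest other split had 16. The 10 splits are too few for a share under 0.05.

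The same limit of 10 splits holds for the counts below. The count of changed genes was 10, with 14 as the highest of the other splits, and 3 of the 10 splits, the real one included, gave at least as many. The genes at fold 2 were 57, with 70 as the highest other, and 6 of the 10 splits, the real one included, gave at least as many. The lists past the threshold with camera were 12, with 10 as the highest other, and the real split was the 1 with the most. On the scaled counts 23 genes changed, with 4 as the highest other, and again only the real split, 1 of 10, reached its count. Among the 100 genes with the smallest p on the scaled counts, 11 pairs lay within 1 Mb of each other without overlap, against a mean of 7.99 in 10000 random draws of 100 tested genes (permutation p = 0.190). These pairs included Gpr6 with Fig4 and Sult2b1 with Ccdc114, which were chosen after their values were seen.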
